A study of Rattus norvegicus with 8 samples.

How the data were processed

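Liver RNA of 8 male F344 rats, 4 fed CDAA with pterostilbene and 4 fed CDAA alone, was extracted with Trizol from frozen tissue and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. Whether the libraries record strand is not given in the sources used here, so reads of overlapping genes on opposite strands may be mixed. The submitters' processing notes list FastQC, TopHat2, Cufflinks, DESeq2 and edgeR without versions, and genome build rn6. The counting tool, the model designs and any filters are not given in the sources used here.

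The single file used is a comparison table of 15115 genes made by the authors, with blocks from DESeq2, edgeR and Cuffdiff, per the file headers. It holds 1 value per gene and comparison, and 0 columns of per-sample values were set aside. The authors' DESeq2 block gives a signal, the mean over all libraries of counts divided by size factors. It also gives the authors' log2 fold change with its standard error, a Wald statistic, here called a score, and a p-value with its adjusted value. The authors' edgeR block gives a log2 fold change, the log2 mean CPM over all libraries, a p-value and an adjusted p-value. The deposited Cuffdiff block gives 1 FPKM value per group, their log2 ratio, a test score, a p-value and a q-value. Adjusted values of the authors' DESeq2 and edgeR blocks matched the Benjamini-Hochberg method when computed again. The log2 fold changes were read as CDAA_PTS over CDAA, and this was checked against the FPKM values of the groups: 512 of 513 genes called by the authors' edgeR block with a Cuffdiff ratio had the same sign, and all 516 had the same sign in the authors' DESeq2 block. The authors' DESeq2 fold changes are moderated toward 0. Their median size relative to the authors' edgeR values was 0.347 for genes under a mean normalized count of 20 and 0.927 at 500 or more.

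The authors' DESeq2 block has no p for 98 genes, 43 of them with a mean of at least 1 CPM, and a p without an adjusted p for 1858 more, none above a mean normalized count of 12.1. These were kept as missing. Cuffdiff did not test 1885 genes for low counts and 3 for low data, and 66 cells of its log2 ratio hold spreadsheet errors and were left out. A Cuffdiff locus identifier is shared by 192 genes, 317 rows share a symbol with another row, and 12 rows have no symbol and go by their Ensembl identifier. Symbols and positions are those of the deposited table. Rows that share a symbol entered gene lists, counts and list tests as separate genes, as the rows of Cyp4a2 did in the fatty acid oxidation list. A separate gene list of another rat assembly, GRCr8, matched 0 identifiers and was not used.

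A quasi-likelihood test on counts had been chosen before the data were examined, but the deposited table has no count per library and could not feed it. The authors' deposited edgeR statistics took its place, with an adjusted p under 0.05 over all genes as the threshold, and the authors' DESeq2 and Cuffdiff statistics served as alternatives. No count model was run here. Standard errors are those of the authors' DESeq2 block, since the authors' edgeR block has none. No spread between rats, exact test or check of single libraries could be made, and p-values measure variation between animals only as the authors' models estimated it. Rats were housed in pairs, and which rats shared a cage is not given in the sources used here.

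Gene lists, the panel and the rule for named genes were fixed before the data were examined. The 38 lists, each with at least 5 measured genes, cover fatty acid synthesis, cholesterol synthesis, fatty acid oxidation and PPAR alpha targets, glycolysis, gluconeogenesis and amino acid breakdown, pentose phosphate, TCA cycle, oxidative phosphorylation, mitochondrial transcripts, AMPK and mTOR, chromatin modifiers, one-carbon metabolism, proliferation, hepatocyte, tumour, stellate cell, macrophage, T and NK cell, B cell, neutrophil, endothelial, cholangiocyte, erythroid, pancreatic acinar and adipocyte markers, aryl hydrocarbon receptor, CAR and PXR, NRF2, NF-kB, interferon, acute phase, unfolded protein, bile acid, male-biased, Wnt, Notch and p53 genes, and immediate early genes. The list test was the competitive camera test of limma 3.58.1 in R 4.3.3 (cameraPR, two-sided, preset inter-gene correlation 0.01). It ran on z-scores made from the authors' edgeR p-values and signs, with Benjamini-Hochberg adjustment over the 38 lists. On simulated statistics for 15115 genes, lists of 20 were called in 3.5% of 200 draws with no shift, 24.5% at a shift of 0.5 z, 83.5% at 1 and 99.5% at 1.5, and 2.9% of 1000 random lists of 20 real genes were called. A call in these draws was an unadjusted p under 0.05. The simulated genes were independent and the real genes were drawn at random. These rates therefore do not cover lists of correlated genes or calls adjusted over the 38 lists. The correlation between list members cannot be estimated without values per library, so calls are also given at a preset correlation of 0.05.

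The rule named the 8 genes with the highest and the 8 with the lowest log2 fold change among genes with an adjusted p under 0.05, a mean of at least 1 CPM and a symbol that is no placeholder. It added up to 3 members with the smallest adjusted p of each list that passed or had at least 3 called members, and the AMPK panel. Its demand that all rats of a group lie on 1 side of the other group could not be checked. It named 54 genes, and other called members of the lists were named after their values were seen. Alternatives were the authors' DESeq2 and Cuffdiff statistics, an adjusted p under 0.1, a change of at least 2-fold, genes of at least 1 CPM with p-values adjusted again, a correlation of 0.05, a rank-based list test and lists without shared genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 did the remaining work. Data of choline-sufficient and resveratrol-fed rats were not analysed here.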

Results

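The samples were livers of male F344 rats fed a choline-deficient, L-amino acid-defined diet (CDAA), a diet used to bring about fatty liver, fibrosis and hepatocellular carcinoma in rats. In the CDAA_PTS group the diet also held pterostilbene, a dimethylated stilbenoid related to resveratrol, at 1.34 g per kg of diet. Per the labels, 4 rats of each diet were sequenced out of 6 in each group of the study, which ran for 60 weeks. CDAA_PTS rats also received the compound in the choline-sufficient diet of the first 3 weeks, and the sample labels give an age of 1 year. The series text gives the short name CDAA+PTS to a resveratrol group as well as to the pterostilbene group; the sample labels name pterostilbene and were followed. The pieces of liver taken in the study included tumours, nodules or normal tissue, and which of these each of the 8 libraries holds is not given in the sources used here. RNA was read as gene-level RNA-seq. The values come from the authors' deposited table, which has 1 row for each of 15115 genes and sets CDAA_PTS against CDAA, so no value per rat was analysed here and depth per library is unknown. The mean normalized counts of the authors' deposited table, taken over all libraries, sum to 1.39e+07 over the genes. The median gene had a mean of 12.9 CPM, the 10 highest genes held 26.6% of the mean CPM, and 17 mitochondrial genes held 5.16%. Positive log2 fold changes mean higher expression with pterostilbene.

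The comparison of CDAA_PTS with CDAA asks how pterostilbene altered liver gene expression on the choline-deficient diet, and the series title places that question around AMPK, the kinase that senses cellular energy. With pterostilbene, the livers had far more mRNA of the xenobiotic-metabolizing cytochromes Cyp1a1 and Cyp1a2. They also had more of enzymes that break down amino acids and handle methyl groups, and less of several fatty acid oxidation genes. The interferon and inflammatory gene lists shifted lower by small medians, with only 2 of 26 and 2 of 19 measured genes called. In the authors' deposited table, 516 of 15115 genes had an edgeR adjusted p under 0.05. Of these, 222 were higher and 294 lower in CDAA_PTS. The DESeq2 columns of the authors' deposited table call 587 genes, 258 higher and 329 lower, and 483 genes were called by both tools. Cuffdiff calls 729 genes, 371 higher and 357 lower with 1 more that has no ratio, so it shows no excess of lower genes, and 349 genes passed in all 3 tools of the authors' deposited table. Most called changes were below 2-fold, since 149 of the 516 had an edgeR change of at least 2-fold, 71 higher and 78 lower.

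**Figure D1:**
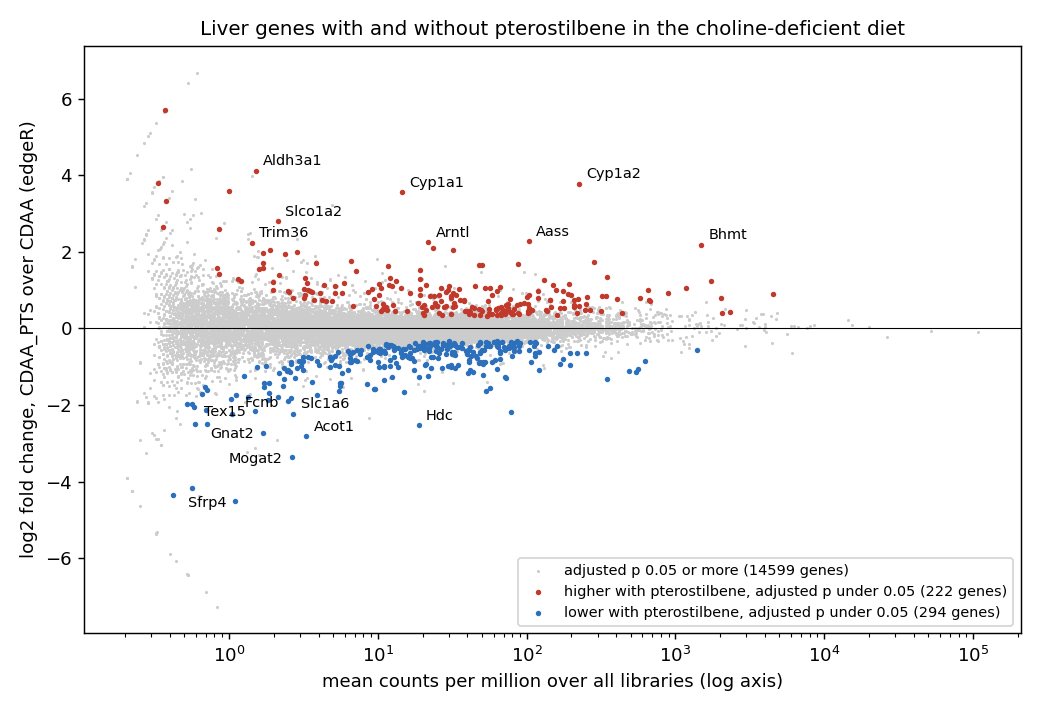
Each point is 1 of 15115 genes, placed by its mean CPM over all libraries (log axis) and its edgeR log2 fold change of CDAA_PTS over CDAA from the authors' deposited table. Red points are the 222 genes higher and blue points the 294 genes lower at an edgeR adjusted p under 0.05, and names mark the 8 genes with the highest and the 8 with the lowest fold changes under the naming rule, from Aldh3a1 at 4.13 to Sfrp4 at -4.51.

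Cyp1a2 and Cyp1a1, the drug- and hydrocarbon-oxidizing enzymes induced through the aryl hydrocarbon receptor, had the smallest adjusted p of the named genes. Cyp1a2 (ENSRNOG00000016173, chromosome 8, 62451328 to 62458301 in rn6 as the authors' deposited table gives it) stood at 213 FPKM in CDAA_PTS and 15.4 FPKM in CDAA. Its edgeR log2 fold change in the authors' deposited table was 3.78 with an adjusted p of 2.7e-23, and its moderated DESeq2 value was 2.43 with an SE of 0.20. Cyp1a1 (ENSRNOG00000019500, chromosome 8, 62472094 to 62478147) rose from 0.811 to 9.50 FPKM, an edgeR log2 fold change of 3.56 with an adjusted p of 3.3e-19 in the authors' deposited table. These neighbouring genes are similar in sequence, so reads shared between them cannot be excluded. Aldh3a1, an aldehyde dehydrogenase of the same receptor's target set, rose by an edgeR log2 fold change of 4.13 with an adjusted p of 0.0029 in the authors' deposited table, from a mean of 1.51 CPM. DESeq2 gives Aldh3a1 no p in the authors' deposited table, so that call rests on edgeR and Cuffdiff. By default DESeq2 withholds a p where a single library is a count outlier, so it cannot be excluded that 1 rat carries the Aldh3a1 value. Of the 6 measured aryl hydrocarbon receptor targets, 3 rose and 3 did not pass, and the same 3 of 6 passed when adjusted over the list alone. The list test gave an adjusted p of 1.8e-13 (limma camera on the deposited edgeR statistics). The members that did not pass, Cyp1b1, Nqo1 and Tiparp, also had log2 fold changes above 0.

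The list that joins glucose output and amino acid breakdown enzymes was shifted upward with pterostilbene. Of 16 measured genes in the list, 3 rose, none fell and 13 did not pass over all genes, against 8 that rose when adjusted over the list alone. The median log2 fold change was 0.46, and 15 of the 16 were above 0 (camera adjusted p = 3.0e-08). G6pc, the catalytic subunit of glucose-6-phosphatase, rose by a log2 fold change of 1.73 with an edgeR adjusted p of 2.4e-14 in the authors' deposited table, from 108 to 359 FPKM. Other glucose output genes were not called. Pck1 and Pc stood at -0.09 and 0.03 (edgeR adjusted p 0.94 and 0.98, authors' deposited table). Fbp1 and Slc37a4 stood at 0.42 and 0.43 (edgeR adjusted p 0.23 and 0.42, authors' deposited table). Hal, which opens histidine breakdown, rose by 0.82 (edgeR adjusted p 0.0042), and Hpd, an enzyme of tyrosine breakdown, by 0.73 (edgeR adjusted p 0.021) in the authors' deposited table. The 8 largest increases under the naming rule included Aass, which carries out the first steps of lysine breakdown, at a log2 fold change of 2.27 (edgeR adjusted p 3.1e-07, authors' deposited table).

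The list for one-carbon, methionine and choline metabolism also shifted upward. Of 23 measured genes, 6 rose, 2 fell and 15 did not pass; adjusted over the list alone, 10 rose and 2 fell. The median log2 fold change was 0.37 (camera adjusted p = 0.00012). Bhmt, which uses betaine made from choline to remethylate homocysteine, rose from 284 to 1303 FPKM, a log2 fold change of 2.18 with an edgeR adjusted p of 3.2e-09 and a DESeq2 value of 1.48 with an SE of 0.20 in the authors' deposited table. Bhmt (ENSRNOG00000011200) lies at 23236574 to 23256158 and its neighbour Bhmt2 at 23272327 to 23289266 on chromosome 2 of rn6, as the authors' deposited table gives them. Bhmt2 rose by 0.83 (edgeR adjusted p 0.0015, authors' deposited table). Dmgdh, Sardh, Cept1 and Mthfd1 were the other members that rose, with edgeR log2 fold changes of 0.84, 0.46, 0.38 and 0.37 in the authors' deposited table. Cuffdiff does not call Sardh, Cept1 or Mthfd1 in the authors' deposited table (adjusted p 0.053, 0.079 and 0.078). Mat2a, the methionine adenosyltransferase that rises in dividing and dedifferentiated hepatocytes, fell by 0.55 (edgeR adjusted p 0.013) in the authors' deposited table.

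Genes of fatty acid oxidation and other PPAR alpha targets were lower, with a median log2 fold change of -0.22 and 24 of 28 measured members below 0 (camera adjusted p = 1.7e-05). Over all genes 4 fell, 2 rose and 22 did not pass, and adjusted over the list alone 5 fell and 2 rose. Acot1, a cytosolic acyl-CoA thioesterase, fell by 2.82 on the log2 scale (edgeR adjusted p 2.3e-11) and Acot2, its mitochondrial relative, fell by 0.94 (edgeR adjusted p 5.1e-08) in the authors' deposited table. Acot1 and Acot2 lie side by side on chromosome 6 and are alike in sequence, so their values may share reads. Cpt1a, which admits long-chain fatty acids into mitochondria, fell by 1.10 (edgeR adjusted p 0.00013), from 140 to 65.4 FPKM, and Vnn1 fell by 1.29 (edgeR adjusted p 0.00015) in the authors' deposited table. Pdk4, which restrains pyruvate oxidation, and Angptl4, an inhibitor of lipoprotein lipase, went the other way and rose by 0.86 and 0.78 in the authors' deposited table (edgeR adjusted p 0.0068 and 0.017). The hour of killing and feeding before death were not tested as causes for these genes.

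Fatty acid synthesis genes moved in both directions and the list did not pass (camera adjusted p = 0.35), with a median log2 fold change of 0.36. That median lay above those of all 10000 random lists matched on expression, while the list test compares mean statistics. Of 19 measured genes, 4 rose, 3 fell and 12 did not pass; adjusted over the list alone, 6 rose and 3 fell. Fasn, Acly, Scd and Gpam, which make and esterify fatty acids, rose by 1.23, 1.01, 0.89 and 0.77 in the authors' deposited table (edgeR adjusted p 0.015, 0.011, 0.029 and 4.5e-05). Elovl2, Fads2 and Fads1, which elongate and desaturate polyunsaturated fatty acids, fell by 1.09, 1.13 and 0.85 in the authors' deposited table (edgeR adjusted p 2.9e-06, 0.00059 and 0.0033). Among 20 glycolysis genes, Pklr rose by 0.85 while Slc16a3 fell by 1.24 and Pfkl by 0.35 in the authors' deposited table (edgeR adjusted p 0.020, 0.029 and 0.038), and 17 did not pass (camera adjusted p = 0.48). Slc16a3 did not pass in DESeq2, with an adjusted p of 0.058 in the authors' deposited table. Cholesterol synthesis genes numbered 24, of which Tm7sf2 and Dhcr7 rose by 0.56 and 0.65 in the authors' deposited table (camera adjusted p = 0.19). For Tm7sf2 Cuffdiff gives a log2 ratio of 0.14 with an adjusted p of 0.87 in the authors' deposited table. Scd and Pfkl were also not called by Cuffdiff (adjusted p 0.059 and 0.15, authors' deposited table).

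Interferon response genes were lower, with 24 of 26 measured members below 0 and a median log2 fold change of -0.12 (camera adjusted p = 0.00024). Over all genes 2 fell and 24 did not pass, and 7 fell when adjusted over the list alone. Gbp2, an interferon-induced GTPase, fell by 0.68 (edgeR adjusted p 0.00089) and the ubiquitin-like modifier Isg15 by 0.57 (edgeR adjusted p 0.016) in the authors' deposited table. The NF-kB and inflammatory cytokine list had a median log2 fold change of -0.28, with 2 of 19 members that fell, none that rose and 17 that did not pass, or 4 that fell when adjusted over the list alone (camera adjusted p = 0.0020). These were the chemokine Cxcl10, which fell by 0.96 (edgeR adjusted p 0.0036), and Tnfaip3, an inhibitor of NF-kB signalling, which fell by 0.55 (edgeR adjusted p 0.044) in the authors' deposited table. Cuffdiff does not call Cxcl10 in the authors' deposited table (adjusted p 0.17).

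The remaining lists that passed were lower by small medians, and each lost its call at a preset correlation of 0.05. Of 18 p53 and apoptosis genes, 1 rose, 2 fell and 15 did not pass, with 2 and 3 when adjusted over the list alone; the median log2 fold change was -0.25 (camera adjusted p = 0.018; adjusted p = 0.11 at correlation 0.05). Cdkn1a, the cyclin-dependent kinase inhibitor, rose by 0.73, whereas Gadd45a fell by 0.51 in the authors' deposited table (edgeR adjusted p 0.0026 and 0.047). Of 21 NRF2 targets, 4 fell, none rose and 17 did not pass, the same counts as when adjusted over the list alone (median log2 fold change -0.12, camera adjusted p = 0.032; adjusted p = 0.17 at correlation 0.05). Srxn1, which repairs oxidized peroxiredoxins, fell by 1.73 and the heme-degrading Hmox1 by 0.62 in the authors' deposited table (edgeR adjusted p 0.00058 and 0.0086). The export pumps Abcc2 and Abcc4 fell by 0.57 and 0.87 in the authors' deposited table (edgeR adjusted p 0.018 and 0.021). Of 36 proliferation genes, 2 fell, none rose and 34 did not pass, the same counts as when adjusted over the list alone (median log2 fold change -0.15, camera adjusted p = 0.036; adjusted p = 0.25 at correlation 0.05). They were the cyclins Ccne1 and Ccnd1, at -1.02 and -0.64 in the authors' deposited table (edgeR adjusted p 0.010 and 0.013). Of the 36, 25 were below 0 and 11 above. The latter included Top2a and Cdk1 at 0.21 and 0.18 (edgeR adjusted p 0.88 and 0.92, authors' deposited table).

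**Figure D2:**
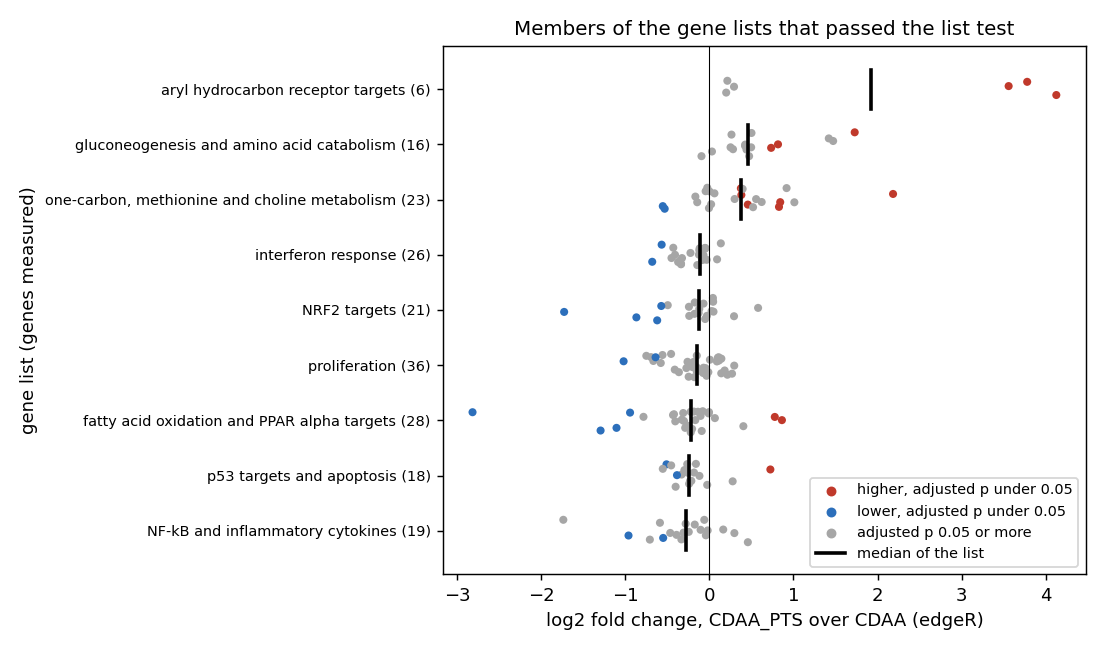
Each point is a measured member of 1 of the 9 gene lists that passed the list test, placed by its edgeR log2 fold change of CDAA_PTS over CDAA from the authors' deposited table; the black bar is the list's median and the number in brackets counts its measured genes. Red and blue mark members with an edgeR adjusted p under 0.05, and the medians run from -0.28 for NF-kB and inflammatory cytokines to 1.93 for aryl hydrocarbon receptor targets.

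Other drug, bile acid and Wnt genes held several called members without a passing list test. Among 13 CAR and PXR targets (camera adjusted p = 0.084), Cyp2b2 rose by 1.15 while Cyp3a9, Abcc2, Cyp3a2 and Cyp3a23/3a1 fell, Cyp3a9 by 0.89 (edgeR adjusted p 0.00038 for Cyp2b2 and for Cyp3a9, authors' deposited table). Cyp3a2 and Cyp3a23/3a1 have the same start and end in the authors' deposited table, and near-identical members of these families may share reads. Of 16 bile acid genes (camera adjusted p = 0.35), the bile acid receptor Nr1h4 and the uptake carrier Slco1b2 rose by 0.46 and 0.71 and Abcc2 fell in the authors' deposited table (edgeR adjusted p 0.015 and 0.039 for Nr1h4 and Slco1b2). Of 14 Wnt and beta-catenin targets (camera adjusted p = 0.70), Notum and Oat rose by 1.04 and 1.66, and Ccnd1 and Myc fell by 0.64 and 1.16 in the authors' deposited table (edgeR adjusted p 0.0083, 0.036, 0.013 and 0.017). Oat did not pass in DESeq2 (adjusted p 0.12, authors' deposited table).

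The panel named by the series title showed no called change. Of 8 AMPK genes, 7 were measured and Prkag1 was not analysed here. None of the 7 passed in edgeR, over all genes or over the panel alone, and 0 had an unadjusted edgeR p under 0.05. DESeq2 and Cuffdiff call 0 of the other 6, while Prkag3, with low counts, has no DESeq2 adjusted p and was not tested by Cuffdiff in the authors' deposited table. The catalytic subunits Prkaa1 and Prkaa2 had DESeq2 log2 fold changes of 0.03 with an SE of 0.09 and 0.17 with an SE of 0.11 in the authors' deposited table (edgeR adjusted p 0.97 and 0.57). Prkab1 and Prkag2 stood at 0.19 and 0.19, and Prkab2, Stk11, the upstream kinase, and Prkag3 at -0.15, -0.17 and -0.27 in the authors' deposited table. These values are moderated toward 0, most of all for Prkag3 with its low counts, where edgeR gives -1.16 (adjusted p 0.39) and Cuffdiff -1.01 in the authors' deposited table. Transcript levels of a kinase do not measure its phosphorylation. In the wider list of 23 AMPK and mTOR genes, the autophagy kinase Ulk1 rose by 0.33 (edgeR adjusted p 0.039, authors' deposited table) and 22 did not pass (camera adjusted p = 0.77). Of 40 DNA methylation and chromatin modifiers, the de novo methyltransferase Dnmt3a fell by 0.33 (edgeR adjusted p 0.048, authors' deposited table), 39 did not pass and the list test gave an adjusted p of 0.98. Cuffdiff calls neither Ulk1 nor Dnmt3a in the authors' deposited table (adjusted p 0.16 and 0.14).

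**Figure D3:**
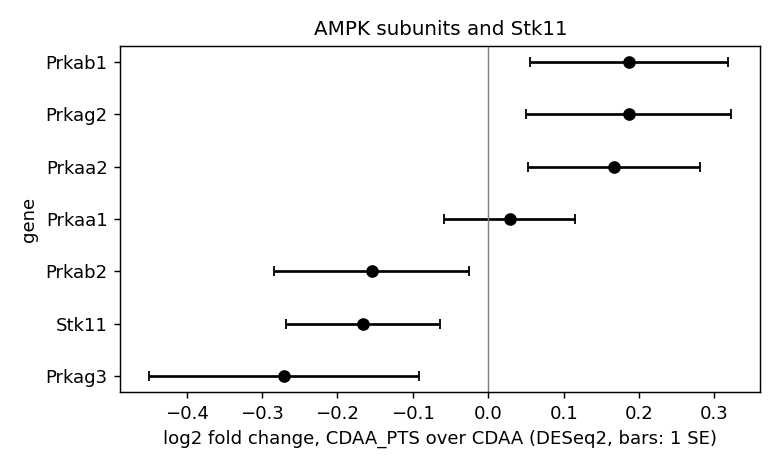
Points are DESeq2 log2 fold changes of CDAA_PTS over CDAA for 7 measured AMPK subunit and Stk11 genes, with bars of 1 SE, both from the authors' deposited table. These moderated values run from -0.27 for Prkag3, where edgeR gives -1.16, to 0.19 for Prkab1, and none of the 7 passed in edgeR.

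The naming rule also listed genes outside these groups, several of them with low counts. Slco1a2, an organic anion carrier, rose by 2.80, the clock transcription factor Arntl by 2.25 and Trim36 by 2.24 in the authors' deposited table (edgeR adjusted p 1.4e-09, 3.1e-08 and 0.028). The labels give no killing times, and circadian genes vary with the hour. Hdc, which makes histamine, the glutamate carrier Slc1a6, Tex15 and the lectin Fcnb were lower, at -2.52, -2.23, -2.16 and -1.91 in the authors' deposited table (edgeR adjusted p 3.6e-06, 5.6e-15, 1.2e-07 and 0.0011). Gnat2 stood at -2.73, Mogat2 at -3.37 and Sfrp4 at -4.51 in the authors' deposited table (edgeR adjusted p 0.0024, 0.046 and 0.016). Mogat2 did not pass in DESeq2 (adjusted p 0.22), and DESeq2 gives Sfrp4 no p in the authors' deposited table. Cuffdiff did not test Sfrp4 either, so its call rests on edgeR alone, and as for Aldh3a1 a single outlying library cannot be excluded. Tex15 was also not tested by Cuffdiff.

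Markers of the cells that a piece of liver can hold did not pass as lists. The hepatocyte list of 24 genes had a median log2 fold change of 0.06 (camera adjusted p = 0.18), with Ass1 alone called, at 0.94 (edgeR adjusted p 0.00076, authors' deposited table). Medians of the other cell lists were 0.05 for 30 stellate cell and matrix genes, -0.09 for 21 macrophage genes, 0.27 for 21 T and NK cell genes, 0.09 for 6 B and plasma cell genes and -0.18 for 8 neutrophil genes (camera adjusted p 0.35, 0.12, 0.18, 0.79 and 0.19). They were 0.09 for 15 endothelial, 0.20 for 16 cholangiocyte, 0.37 for 7 erythroid, -0.91 for 5 pancreatic acinar and -0.14 for 7 adipocyte genes (camera adjusted p 0.35, 0.80, 0.19, 0.98 and 0.35). Among random lists matched on expression, the cholangiocyte, erythroid and T and NK cell medians lay at percentiles 99.72, 99.03 and 98.56. The acinar median lay at 0.55, and those of the remaining cell lists between 5.13 and 94.97. A difference in cell content is therefore not excluded. Called members of the lists other than hepatocytes were Tgfb1, Gpnmb and Fabp4, which fell by 0.55, 0.46 and 0.94 in the authors' deposited table (edgeR adjusted p 0.036, 0.013 and 0.0025). Cuffdiff does not call Tgfb1, Abcc2 or Fh in the authors' deposited table (adjusted p 0.061, 0.084 and 0.096). In 20 preneoplasia and tumour markers (camera adjusted p = 0.79), Aldh3a1 rose and Lgals3, a galectin, fell by 0.60 (edgeR adjusted p 0.0015, authors' deposited table). Crp was called among 15 acute phase genes, at 1.05 (edgeR adjusted p 3.1e-07, authors' deposited table; list adjusted p = 0.18). Other lists did not pass: nuclear-encoded oxidative phosphorylation (28 genes, 0.48), mitochondrial transcripts (11 genes, 0.57), TCA cycle (16 genes, 0.60, with Fh called at 0.38 in the authors' deposited table), pentose phosphate (7 genes, 0.99), Notch (18 genes, 0.42), male-biased genes (7 genes, 0.78, with Cyp3a2 called), the unfolded protein response (20 genes, 0.78) and immediate early and heat shock genes (14 genes, 0.26), with the camera adjusted p after each count. Atf3, in the last pair of lists, fell by 1.58 (edgeR adjusted p 9.0e-05, authors' deposited table). The median and the mean statistic differed in sign for male-biased genes, pancreatic acinar genes and chromatin modifiers.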

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

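No paired analysis was possible because the deposited table gives no value per rat, and the rat numbers name different animals. For the same reason other normalizations and filters, limma-voom, the non-robust fit, estimated correlations, fry and leaving out each rat in turn were not run, and whether a single rat sets a call is unknown, as is depth per library. Pseudocounts did not apply. The Cuffdiff, combined-tool and mean CPM settings, the larger preset correlation, the rank-based test and the other statistics for lists were chosen after seeing the data.

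Against 516 genes called, the count was 797 at an adjusted p under 0.1 and 149 with at least a 2-fold change, which follow from the thresholds. It was 587 with the authors' DESeq2 columns, 729 with Cuffdiff, 543 among genes of at least 1 CPM and 349 in all 3 tools. The 9 gene lists that passed became 9 with DESeq2 statistics, 11 with Cuffdiff, 9 at a mean of at least 1 CPM, 8 by ranks, and 6 both at a preset correlation of 0.05 and without shared genes. The aryl hydrocarbon receptor list has too few genes for the last setting. At correlation 0.05 the adjusted p was 0.248 for proliferation, 0.170 for NRF2 targets and 0.107 for p53 targets. Without shared genes, it was 0.1003 for proliferation and 0.0733 for NRF2 targets, and by ranks it was 0.0803 for NRF2 targets. The larger correlation widens the null by construction. Without shared genes the proliferation list lost only Ccnd1, which the Wnt list also holds. Its unadjusted camera p then went from 0.0085 with 36 genes to 0.022 with 35. For NRF2 targets without shared genes or by ranks, the cause was not tested. All other passing lists kept their direction and call under the alternatives that ran.

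With Cuffdiff statistics the erythroid list (adjusted p 0.0105) and CAR and PXR targets (adjusted p 0.0317) also passed; the cause was not tested. Lists that never passed changed sign near 0. These were pentose phosphate (adjusted p 0.960 with Cuffdiff, 0.999 without shared genes), chromatin modifiers (0.962 by ranks, 0.992 at 1 CPM), tumour markers (0.915 with DESeq2, 0.915 without shared genes), acinar genes (0.962 by ranks), the unfolded protein response (0.914 without shared genes) and male-biased genes (0.960 with Cuffdiff). The AMPK panel had 0 called genes of 7 in edgeR and 0 of 6 in DESeq2 and in Cuffdiff, where Prkag3 has no adjusted p or was not tested. Of the single genes listed by the rule or afterwards, 5 lost their call in DESeq2 and 25 in Cuffdiff, 9 gained a call in Cuffdiff, and none changed sign. DESeq2 gives Aldh3a1 and Sfrp4 no p.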

Other observations

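The gene lists and tests in this part were chosen after the results were seen, except the immediate early and heat shock list with its test and the hepatocyte, other cell, glucose output and amino acid breakdown, and one-carbon lists, which were fixed beforehand. Gene values are edgeR log2 fold changes of the authors' deposited table unless another tool is named. Camera adjusted p in this part are adjusted over the 9 lists chosen here unless stated, and they run too small for lists picked for their values. A list of AP-1, C/EBP and related early transcription factors, such as Myc, Klf6 and Bcl3, was lower in CDAA_PTS: of 20 measured genes 9 fell, none rose and 11 did not pass, with a median of -0.65 and 5 above 0 (camera adjusted p = 2.9e-10). The immediate early and heat shock list fixed beforehand did not pass (median -0.05, 6 of 14 above 0, camera adjusted p = 0.26 over the 38 lists). Of the former list, Jund fell by 0.97, Maff by 1.46, Atf3 by 1.58 and Cebpd by 1.39 in the authors' deposited table (edgeR adjusted p 1.3e-06, 6.9e-05, 9.0e-05 and 0.0012). Actin cytoskeleton genes fell as well, 4 of 24 measured, none rose and 20 did not pass (median -0.16, camera adjusted p = 5.1e-06), with Pfn1 and Vasp down by 0.57 and 0.62 in the authors' deposited table (edgeR adjusted p 8.3e-05 and 0.00027). Of 29 measured rows for the 28 symbols of a list made mainly for tryptophan, lysine, tyrosine and glycine breakdown, 10 rose, none fell and 19 did not pass (median 0.44, camera adjusted p = 1.4e-15). The 10 include Aass, Hal and Hpd, which were already named above. They also include Ftcd, which like Hal acts in histidine breakdown, and Etnppl, an ethanolamine-phosphate lyase. The kynurenine enzymes Kynu and Kmo rose by 0.99 and 0.64 in the authors' deposited table (edgeR adjusted p 1.8e-06 and 0.00033). Among 11 acyl-CoA thioesterases, the neighbouring Acot1, Acot2, Acot3 and Acot4 fell while the median was -0.03.

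DESeq2 by default withholds a p where the count of a single library is an outlier, and the authors' deposited table has 98 genes without a p, 43 of them with a mean of at least 1 CPM. Among them were Igf2, at 4.80 FPKM in CDAA_PTS and 8.39 in CDAA, and Mir675, at 22.9 and 92.4 FPKM, which lie close together on chromosome 1. Tat, Got1, Scd2, Epdr1, Myh11 and Acta2 were also among them in the authors' deposited table. None of these 8 passed in edgeR, and Cuffdiff calls some of them, such as Got1 at a log2 fold change of 1.45 (adjusted p 0.0019). edgeR does call 5 of the 98, which include Aldh3a1 at 4.13 and Sfrp4 at -4.51, the ends of the named genes, and LOC367746 at 3.58 in the authors' deposited table. The others are AABR07026778.1 at 1.96 and AABR07028989.1 at -4.18, and Cuffdiff calls Aldh3a1 and AABR07026778.1 alone among the 5. The authors do not say why these p are missing, and whether single rats carry these values was not analysed here.

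Circadian clock genes called by edgeR moved in opposite directions. In the authors' deposited table Arntl, Npas2, Nfil3 and Clock rose by 2.25, 1.54, 0.88 and 0.48, and Dbp, Per2, Per3 and Wee1 fell by 1.57, 1.14, 1.06 and 0.91. The medians were 0.68 for 6 genes of the Arntl arm and -0.88 for 12 of the Per and Dbp arm, a difference of 1.56 between genes picked after their values were seen. In the Arntl arm 2 of 6 did not pass and in the other arm 8 of 12, among them Nr1d1 at -0.04 (edgeR adjusted p 0.98, authors' deposited table). Dbp did not pass in DESeq2 (adjusted p 0.063), and Clock and Per3 did not in Cuffdiff (adjusted p 0.097 and 0.42), which gives Per3 a log2 ratio of -0.55 in the authors' deposited table. Livers taken at different hours may give this difference, and so may an effect of pterostilbene on the clock, and these cannot be told apart because the labels give no killing times.

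Amino acid breakdown and one-carbon genes rose together, with a median of 0.42 over the 39 genes of both lists. A larger share of hepatocyte RNA in CDAA_PTS would raise hepatocyte markers by as much, but their median was 0.06 with an upper 95% bootstrap bound of 0.19. The lower bound was 0.008 and 18 of 24 markers were above 0, so a smaller contribution of hepatocyte share is not excluded. The bootstrap draws marker genes and does not measure spread between rats. The marker list was not made to separate normal liver from nodule or tumour tissue, so a difference in such tissue was not tested. Of the 10 lists for other cells, 6 had a median above 0 and 4 below. Pterostilbene, the kind of tissue taken, feeding before death and the hour of killing, since many such genes follow the clock, stay open and untested. For the fatty acid oxidation and synthesis genes the same causes were not tested either.

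Histone transcripts were lower: of 34 measured rows, which carry 29 symbols, 8 fell, none rose and 26 did not pass, with a median of -0.64 (camera adjusted p = 9.3e-12). DESeq2 calls 7 of them and Cuffdiff 3. Lower capture of RNA without a poly(A) tail would lower other such RNAs alike, yet 291 such small RNAs had a median of -0.02 with a lower 95% bootstrap bound of -0.087. Most of these have low counts, and snoRNAs lie within other genes. The 39 with a mean of at least 1 CPM that are not snoRNAs had a median of 0.05 with a lower bound of -0.12. The 291 rows carry 147 symbols and were drawn as if independent. Their median lay at percentile 1.5 among random lists matched on expression, so a slight drop among them is not excluded. Of the 291, edgeR calls Terc and snoMBII-202 lower, at -0.75 and -1.99, and a copy of 7SK higher, at 0.44, in the authors' deposited table. Whether CDAA_PTS livers had fewer cells in S phase stays open: 36 S phase genes without histones had a median of -0.17 with a 95% bootstrap interval of -0.34 to -0.07, which does not reach the histone median (camera adjusted p = 0.0019, and unadjusted p = 0.028 at a preset correlation of 0.05), and 0 of them passed in edgeR, 7 had an unadjusted p under 0.05, and DESeq2 calls 0 and Cuffdiff 2. Reads shared between histone copies, and whether the pieces of liver differed in tumour content, were not tested.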
